A study of Caenorhabditis elegans with 4 samples.

How the data were processed

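Chromatin of synchronised L2 hermaphrodites grown at 20 °C on HB101 bacteria was crosslinked with 2% formaldehyde, sheared by sonication and precipitated with affinity-purified antibodies against GFP, per the labels' protocols. Part of each lysate was kept as Input. Samples were grouped by their titles into ChIP (2 samples) and Input (2 samples), with the replicate numbers that the titles give.

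The deposited files analysed here are 3 peak lists: 1 for each ChIP sample and 1 labelled combined. Peaks were called with PeakSeq, which compares ChIP reads with scaled control reads, on WormBase WS220 coordinates, per the file headers and the columns of the files. For each peak, the authors deposited a q-value and the first and last base. The q-values of all 25802 peaks were below 0.01, and the value stood in 2 columns that were identical for every peak. The aligner, the PeakSeq version and settings, the control reads used and the way the combined list was made are not given in the sources used here. In the replicate 2 list, 1 peak was commented out with a message about converting coordinates, so at least that list had been moved to WS220 from another build. Neighbouring peaks were never closer than 200 bp. Peak names in all 3 lists began with GEI-11 although the labels name NHR-129. No list gives read counts, summits or fold enrichment. The depth is therefore unknown, a longer list can come from deeper sequencing, and q-values were used only to rank, class or filter peaks within a list. Sums of -log10 q-values over both replicates serve to order and class shared loci and not as a signal level.

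Peaks were compared by position with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plotted with Matplotlib 3.10.9. Peaks counted as shared when they overlapped by at least 1 bp. The replicated set consists of combined regions overlapped by both replicate lists, placed by their midpoints. Chance overlap came from 1000 random placements of peaks within the span of their own chromosome (one-sided), or from 100 for the alternatives that ask for 50% overlap or for centres within 100 bp. A second chance value, added later, shifted all peaks of a chromosome together by 20 to 200 kb and gave 8.04% for replicate 1 in replicate 2. Shares carry 95% Wilson intervals, which cover counting error only. Densities were counted in 1-Mb bins (end bins of at least 0.5 Mb were scaled to their length). They were compared by two-sided permutation tests of the difference of means with 100000 resamples, or by exact enumeration for the middle of each chromosome, the central of 3 equal parts, against the rest. Benjamini-Hochberg adjustment was made within each family of 6 or 12 tests. The overlap count was tested on copies of the 7583 replicate 1 peaks, with part of them moved to places free of replicate 1 peaks. It returned the planted shares of 30.4% and 69.6% exactly, as this construction requires of a correct count. For the 2 replicate lists themselves, chance overlap came to 7.19% where 7.20% was computed from the gaps. A planted density ratio of 3 was returned as 2.98 over 5211 simulated regions. Of 200 simulated comparisons of independent bins without a difference, 5.5% gave a permutation p under 0.05. Real bins lie side by side and varied more, while the test treats bins as interchangeable. The error rate for real bins is therefore unknown.

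The planned tests and alternatives were fixed before the data were examined. No genome or gene annotation of WS220 was used here, so several of them were not run: the share of regions in promoters, the occupancy of 29 gene groups, the strength of regions at promoters, non-coding gene classes, the content of 11 sequence motifs, and the peaks over nhr-129 and unc-119. The planned Fisher's exact test on promoters of X and autosomal genes was replaced by the permutation test over bins. The gene table used here belongs to WBcel235, another assembly, and served only for numbers of protein-coding genes per chromosome and for the chromosomes of nhr-129 (V) and unc-119 (III). The naming rule, also fixed in advance, took nhr-129, unc-119, the 15 replicated regions with the best mean rank of the q-value in both replicates, and members of gene groups. Its parts on gene groups and on the gene nearest to each region could not be applied. The contrasts of V, of the IV segment, of regions of 500 bp or more, of chromosome middles and of loci absent from the combined list were all chosen after the data had been examined. Alternatives covered the overlap rule, a stricter q-value limit (the strongest 50% of a list), the set of regions, each replicate list alone, region width and merging distance.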

Results

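Binding regions of NHR-129, a member of the nuclear hormone receptor family of transcription factors, were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caenorhabditis elegans hermaphrodites at the L2 larval stage. The worms carried a transgene that expresses NHR-129 fused to green fluorescent protein (GFP), in a background mutant for unc-119 and rescued by an unc-119 copy on the same construct. The labels place the fusion protein in seam cells (lateral skin cells that divide like stem cells through larval life), in the pharynx (the feeding organ) and in head neurons. Chromatin was collected with antibodies against GFP. The 4 samples were 2 ChIP samples and 2 Input samples of total chromatin, numbered as replicates 1 and 2. Peak lists were analysed for both ChIP samples, together with 1 combined list; no separate list of an Input sample was analysed here. The lists give the position and the q-value of each peak but no read counts, so the sequencing depth behind each list is unknown. The labels do not say whether the replicates came from separate cultures, so differences between them measure only the spread between these samples, which may be technical. The p-values come from random placements and from bins within these samples, and do not cover variation between cultures. Every peak name in the 3 lists carried GEI-11, the name of another protein, and none carried NHR. The lists are therefore described as those of the ChIP labelled NHR-129.

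The ChIP labelled NHR-129 gave mostly narrow regions on all 6 chromosomes. Replicate 1 held 7583 peaks, replicate 2 held 7109 and the combined list held 11110. The peaks covered 3.64 Mb, 3.25 Mb and 5.32 Mb, in the same order. Median widths were 362 bp in replicate 1 (interquartile range 196 to 562 bp), 352 bp in replicate 2 (188 to 545 bp) and 358 bp in the combined list (188 to 570 bp). Some peaks were very short: 228 peaks of replicate 1, 245 of replicate 2 and 340 of the combined list were 10 bp or shorter. The widest combined regions lay at IV 11979111 to 11986868 (7758 bp), II 8741174 to 8748173 (7000 bp) and X 8016641 to 8023412 (6772 bp). These 3 regions were singled out after their widths were seen, and all coordinates are those of WormBase WS220. The authors' q-values ran from just under 0.01 down to 9.72e-294 in replicate 1, 4.81e-289 in replicate 2 and 2.92e-294 in the combined list. They are used to rank, class or filter peaks within a list, and summed over the replicates only to order shared loci.

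The first comparison asked how far the replicates found the same regions. Of the 7583 replicate 1 peaks, 5439 overlapped a replicate 2 peak by at least 1 bp, or 71.7% (95% Wilson interval 70.7 to 72.7%, counting error only). In the other direction, 5517 of 7109 peaks overlapped, or 77.6% (76.6 to 78.6%). Random placement of the replicate 1 peaks within their own chromosomes gave 7.19% on average and 8.31% at most, so the observed share was 9.97 times the random mean. The one-sided permutation p from 1000 placements was 0.001, the smallest they can give. The same p was reached for the reverse direction, where random placement gave 7.69%. Random placement treats every position of a chromosome as equally likely. Overlap above it therefore cannot tell binding from background that both samples share.

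Strong peaks were shared almost without exception, and weak peaks often were not. All 758 peaks in the strongest decile of replicate 1 overlapped a replicate 2 peak, against 34% of the weakest decile. For replicate 2 the shares were 99.7% and 46.1%. Across the 5439 shared peaks the q-values of both replicates ranked similarly (Spearman's rho 0.865, a description across peaks, which are not independent replicates). On V, 62.1% of the replicate 1 peaks (60.5 to 63.7%) overlapped a replicate 2 peak, against 76.4% on IV and up to 87.6% on III among the other chromosomes. For replicate 2 the share was 69.5% on V, 77.5% on IV and between 83.5% (II) and 89.2% (X) elsewhere. Within IV, the segment from 12 to 15 Mb had shares of 70.9% in replicate 1 and 65.8% in replicate 2. The unshared peaks of V were mainly its narrowest. Of 953 replicate 1 peaks under 100 bp on V, 16.2% were shared, while 99.4% of the 501 peaks of 500 bp or more on V were shared. Outside V and the IV segment, 90.7% of the replicate 1 peaks of that width were shared. Peaks under 100 bp made up 26.1% of the V peaks of replicate 1 and 28.6% of those of replicate 2. Chromosome V, the IV segment and the width classes were singled out after the data had been examined.

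The combined list held many weak regions that neither replicate list contained. Of its 11110 regions, 5386 were overlapped by peaks of both replicates, or 48.5% (95% Wilson interval 47.6 to 49.4%). Another 1647 regions (14.8%) were overlapped only by replicate 1 and 1083 (9.75%) only by replicate 2. The remaining 2994 regions (26.9%, interval 26.1 to 27.8%) were overlapped by neither. Regions found in both replicates had a median -log10 q-value of 18.2 and a median width of 491 bp. Regions found in neither had medians of 3.27 and 239.5 bp. The 100 strongest combined regions were all overlapped by both replicate lists. In the strongest 50% of the combined list, 87.6% of regions were found in both replicates. The 5386 regions form the replicated set, on which the results on position rest.

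The 15 replicated regions with the best mean rank in both replicates were spread over every chromosome: 4 lay on V, 4 on X, 3 on IV, 2 on III, 1 on I and 1 on II. The leading region, V 4041832 to 4042502 (671 bp), ranked 17 in replicate 1 and 12 in replicate 2, with a combined q-value of 1.07e-277. It was followed by V 10466315 to 10467587 (combined q-value 1.92e-291) and V 5080624 to 5081785 (1.47e-224). The next were II 11633616 to 11636227 (1.18e-273) and X 6250080 to 6256114 (1.42e-292), the latter 6035 bp wide. On III, the regions were 832025 to 836240 (5.17e-193) and 12612119 to 12617433 (1.61e-262), and the region on I was 7491665 to 7493342 (5.38e-246). The 3 regions of IV began at 13394371, 13887053 and 14619457 and ended at 13395772, 13888825 and 14624353, all within a dense segment of IV between 12 and 15 Mb. X also held 3114261 to 3117627, 4007371 to 4009362 and 8035894 to 8036979, and V held 16591854 to 16595719. No gene is assigned to these regions, because no gene annotation of WS220 was used here.

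These 15 were not the strongest loci of the replicate lists, since a group of stronger loci shared by both replicates had no counterpart in the combined list. Replicate peaks merged within 200 bp made 5500 shared loci, of which 30 were not overlapped by any combined region. These 30 comprised 23 loci on V, 3 on X, 2 on I and 2 on IV, with a median width of 2955 bp against 457 bp for the loci present in the combined list. Strength was taken as the sum of the -log10 q-values of both replicates. By this measure, 23 of the 100 strongest shared loci were absent (23%), against 7 of the 5400 others (0.130%). All 10 loci with a sum above 400 were absent, as were 9 of 15 between 300 and 400, 4 of 61 between 200 and 300 and 2 of 4689 below 50. The 6 absent loci with sums below 150 all lay within 362 bp of a stronger absent locus. This comparison, its limits and the loci named from it were chosen after the values had been seen.

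The strongest absent locus, X 6735314 to 6745985, was 10672 bp wide and had q-values of 9.72e-294 in replicate 1 and 4.81e-289 in replicate 2, the smallest of both lists. The next 4 lay on V at 14685563 to 14689637, 10940023 to 10941426, 11531720 to 11535026 and 15566344 to 15570148. Their replicate 1 q-values were 8.56e-282, 1.31e-288, 4.1e-290 and 2.58e-257. Of the 20 strongest peaks of either replicate list, only 4 overlapped a combined region. A pair of strong peaks of replicate 2 was missing from both other lists: I 7079000 to 7086243 (q-value 4.67e-274) and V 5779873 to 5781144 (8.87e-280). With peaks merged within 1000 bp in place of 200 bp, 8 shared loci were absent from the combined list.

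**Figure D1:**
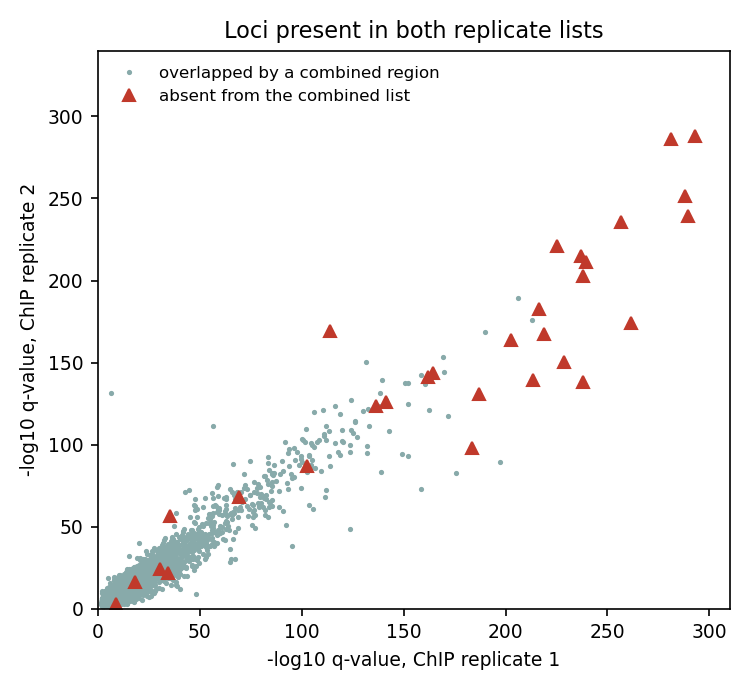
Each point is 1 of the 5500 loci present in both replicate lists, placed by its -log10 q-value in ChIP replicate 1 (x axis) and ChIP replicate 2 (y axis). Red triangles are the 30 loci absent from the combined list, which hold all 10 loci with a summed value above 400; grey-green dots are loci overlapped by a combined region.

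The distribution of the replicated set over the chromosomes was uneven, and chromosome V stood apart. V held 2288 of the 5386 regions, or 42.5%, while it carries 25% of the 19971 protein-coding genes counted in the WBcel235 annotation. Its density was 109 regions per Mb, against 45.2 on IV, 43.4 on III, 39.4 on I, 35.3 on II and 33.2 on X. Per 100 protein-coding genes, V held 45.8 regions and the other chromosomes between 15.6 (II) and 24 (IV). Both replicate lists showed the excess on their own: V held 48.1% of replicate 1 peaks (95% Wilson interval 47.0 to 49.2%) and 46.5% of replicate 2 peaks (45.3 to 47.7%). In 1-Mb bins, V had 109 ± 33.4 replicated regions per Mb (SD, 21 bins) and the other chromosomes 39.3 ± 18.5 (SD, 79 bins), a ratio of 2.78. The two-sided permutation test over bins, chosen after the counts per chromosome had been seen, gave p = 1e-05, the smallest that 100000 resamples can give, and 6e-05 after Benjamini-Hochberg adjustment over 6 tests. Bins are neighbouring stretches of the same samples and not independent replicates.

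V regions were narrower than those elsewhere, and the ratio of V to the other chromosomes was smaller among wide regions, a difference that was not itself tested. The median width of the replicated regions was 364 bp on V and between 568.5 bp (IV) and 652 bp (X) elsewhere. Among regions of 500 bp or more, V had 32.9 ± 14.1 regions per Mb (SD, 21 bins) and the other chromosomes 24.5 ± 9.35 (SD, 79 bins). That ratio was 1.34, with a two-sided permutation p of 0.00167 (adjusted 0.00501). In the deposited lists, V lay within the range of the other chromosomes at this width. It had 33.2 regions of 500 bp or more per Mb in the combined list, with the others between 31.8 (II) and 36.3 (X). Replication kept nearly all of these on V (32.9 per Mb) but fewer elsewhere (between 21.5 on II and 26.6 on IV). V therefore lay above all others at this width only after that filter, and the cause of the ratio of 1.34 was not tested. In replicate 1, V had 24 per Mb, with the others between 19.7 and 24.6, and in replicate 2 it had 19.4, with the others between 18.7 and 22.2. At similar q-values, V regions had smaller median widths than those of the other chromosomes, without IV 12 to 15 Mb, in all 6 classes of q-value. In the 5 classes with at least 20 regions on V, the median width on V was 0.426 to 0.597 times that elsewhere. A limit of 500 bp is therefore not matched for strength between V and the others. At -log10 q-values from 40 to 100, V held 467 regions and these others 347, in the replicated set and in the combined list alike. From 5 to 10, the replicated set held 276 on V and 661 on the others. Densities at matched q-values were not tested. Narrow regions were not particular to V. In all 6 classes the median width in the IV segment lay below that of the rest and above that of V. For -log10 q-values from 10 to 20, the medians were 460 bp in the IV segment, 537.5 bp in the rest and 275 bp on V.

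**Figure D2:**
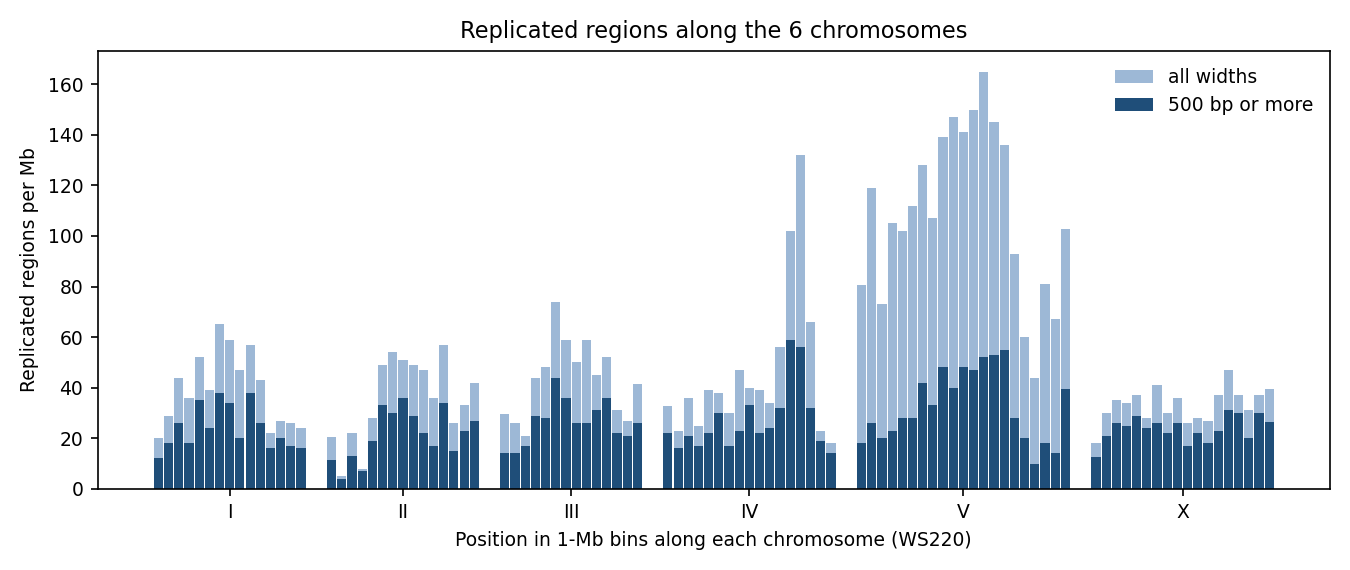
Bars give the replicated regions per Mb in 1-Mb bins along each chromosome, for all widths (light) and for regions of 500 bp or more (dark, drawn in front). Bins of V range from 44 to 165 regions per Mb, while the median bin of the other chromosomes holds 37.

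**Figure D3:**
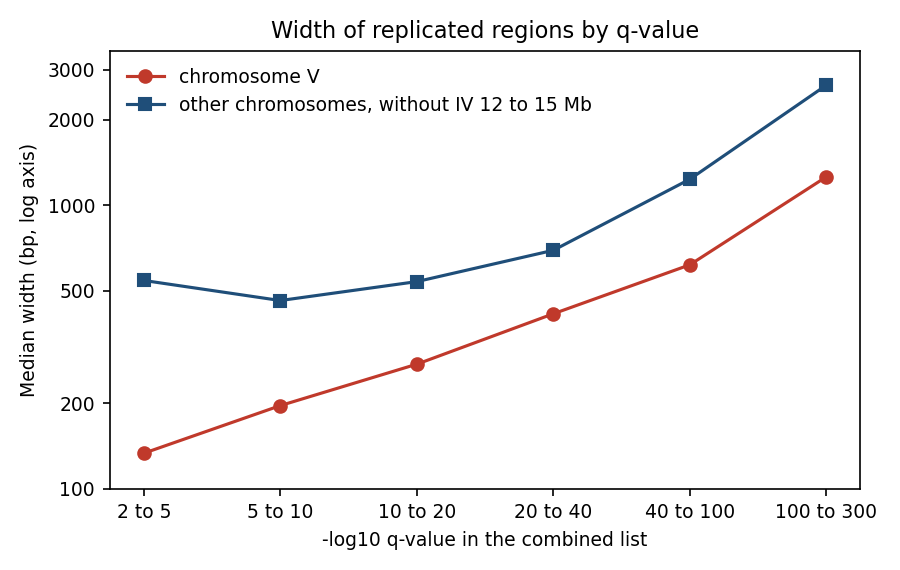
Points give the median width in bp (log axis) of replicated regions in 6 classes of -log10 q-value, for V (red circles) and for the other chromosomes without IV 12 to 15 Mb (blue squares). V lies below the others in every class; the class from 2 to 5 holds only 4 regions of V.

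A segment of IV was also dense. Between 12 and 15 Mb, IV held 100 ± 33 replicated regions per Mb (SD, 3 bins), against 34.3 ± 10.2 in the rest of IV (SD, 14 bins), a ratio of 2.91. Among regions of 500 bp or more the values were 49 and 22.3 per Mb. In windows of 0.5 Mb, the density rose from 64 per Mb between 11.5 and 12 Mb to 176 per Mb between 12 and 12.5 Mb. It fell to 28 per Mb between 12.5 and 13 Mb, rose again to 168 per Mb between 13 and 13.5 Mb, and was down to 12 per Mb between 15.5 and 16 Mb. The dip between 12.5 and 13 Mb was present in each replicate list: replicate 1 had 270, 46 and 224 peaks per Mb in the 3 windows from 12 to 13.5 Mb, and replicate 2 had 276, 36 and 256. The segment was chosen because it looked dense, so no test was made on it.

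X, whose gene content and dosage compensation differ from those of the autosomes, had fewer replicated regions per Mb than the autosomes, but this difference did not pass the test once V was left out. X had 33.3 ± 6.67 regions per Mb (SD, 18 bins) and the autosomes 58.6 ± 38.5 (SD, 82 bins), a ratio of 0.568. The two-sided permutation test gave p = 0.00632, adjusted 0.0126. Against the autosomes without V, at 41.1 ± 20.4 regions per Mb (SD, 61 bins), the ratio was 0.810 and the permutation p 0.112 (adjusted 0.169). Among regions of 500 bp or more, the ratio of X to all autosomes was 0.889 (permutation p 0.298, adjusted 0.358). The last 2 comparisons were added after the data had been examined. All of these tests treat neighbouring bins as interchangeable, so their p-values may be too small.

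Replicated regions were denser in the middle of I, II, III and V than towards the ends, with each chromosome divided into 3 equal parts. The ratio of the middle to the rest was 1.65 on I (adjusted exact permutation p = 0.015), 1.80 on II (0.0224), 1.66 on III (0.012) and 1.53 on V (0.00588). On V the densities were 142 ± 17.6 per Mb (SD, 7 bins) in the middle and 93.1 ± 26.7 (SD, 14 bins) outside it. IV and X did not pass the test, with ratios of 0.844 (adjusted exact permutation p = 0.701) and 0.916 (0.485). The outer parts of IV hold the dense segment. Without its 3 bins the ratio on IV was 1.40, which was not tested because the bins had been chosen for their density. All 12 tests of this family, over 6 chromosomes and both width limits, were two-sided and chosen after the data had been examined. They treat bins as interchangeable, although each middle is 1 unbroken stretch and neighbouring bins can resemble one another. Their p-values may therefore be too small. Among regions of 500 bp or more, I, II and V passed with ratios of 1.51, 1.76 and 1.74, while III had a ratio of 1.38 and an adjusted exact permutation p of 0.111.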

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

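The test on peak names was chosen after the names had been seen. All 25802 peak lines of the 3 lists carried the name GEI-11, in a column outside the positions and q-values used for the comparisons, while the labels and the series title name NHR-129. A candidate explanation is lists of another factor deposited under these labels: the number of peak lines whose name holds NHR was 0. A naming template left over from another run would give the same count, so these explanations cannot be told apart from the names. Peaks over nhr-129, which the transgene carries in added copies, were not analysed here, and no biological explanation was tested.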

How the results depend on the processing

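Alternatives with 500-bp regions, without V or the IV segment, a shifted chance value, shared replicate 1 peaks, merging distances or chromosome V itself were added after the data had been examined; the others were planned. Of 29 alternatives to 11 results, 23 kept the direction and the side of the threshold, or stayed within the spread. Replicate overlap ran from 61.4% to 81.8% and stayed above chance in each (one-sided permutation p at the smallest the placements can give, 0.001 or, for the 50% and centre rules with 100 placements, 0.01). The V ratio was 3.28 and 3.50 in the lists of single replicates, and the X ratio 0.492 and 0.515. In the strongest 50% of the replicated set, the V ratio was 3.52 and the X ratio 0.517. At 500 bp or more the V ratio fell from 2.78 to 1.34 but kept its direction and side of the threshold in the replicated set. In the 3 deposited lists, V lay within the range of the other chromosomes at this width. The share of combined regions found in both replicates moved to 87.6% in the strongest 50%, by construction without the weak regions. The X to autosome ratio lost its call at 500 bp or more (0.889) and without V (0.810); the second removes the dense chromosome itself, and the cause of the first was not tested. Absent loci fell from 30 to 8 when peaks were merged within 1000 bp: 26 of the 30 then lay in wider loci that overlap a combined region, and the other 4 formed 3 loci, while 5 of the 8 held none of the 30. The middle of III lost its call at 500 bp or more (1.38); the ratio for IV was 1.40, untested, without the segment chosen for its density. Without an annotation of WS220, the alternatives for promoters, gene groups, region strength, non-coding genes and motifs, and chance placement within promoters, were not run. No paired analysis was possible because no list of an Input sample was analysed here. The unknown depth limits every comparison of list lengths.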

Other observations

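All tests in this part were chosen after the patterns had been seen. The first pattern is the excess of regions on V. A larger number of genes on V does not account for it, because V still held 2.21 times as many replicated regions per protein-coding gene as the other chromosomes. A candidate explanation is that ChIP coverage exceeded the scaled input along the whole of V. The lowest bin of V held 44 replicated regions per Mb, above the median bin of the others (37) but below their 95th percentile (65.1). This restates the excess and would also hold with more ordinary sites, so it cannot decide. In every class of q-value the median width on V was at most 0.597 times that elsewhere without IV 12 to 15 Mb (at most 0.673 in the deposited lists). Narrow regions on V had been seen before, and those of the IV segment were narrower than the rest too, so this cannot decide either. More binding sites of the ordinary kind on V stay open. Regions of 500 bp or more were raised in the replicated set (1.34), where replication kept a larger share of them on V than elsewhere. They were not raised in the deposited lists (24 per Mb on V in replicate 1, 19.4 in replicate 2 and 33.2 combined, within the range of the others). A fixed width limit also removes more of the narrow V regions. Coverage itself was not analysed, and no biological explanation was tested.

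The second pattern is the absence of the strongest shared loci from the combined list. Loss of regions when coordinates were converted to WS220 would follow position or width and not strength. Among shared loci of 2000 bp or more, 84.2% were absent at strength sums of 300 or more (16 of 19) and 0 of 136 at sums under 150. Width alone therefore does not account for the absence. Position was not compared, although 23 of the 30 absent loci lay on V, and the strength limits were chosen after the values had been seen. Strong regions that were kept also lay often on V. At -log10 q-values from 100 to 300, the combined list held 137 regions on V, 13 in the IV segment and 91 elsewhere. A candidate explanation is that q-values too small to be stored became 0 and were lost. No list held a q-value of 0, and the largest -log10 q-value in any list was 294, but lists without such a loss could show this too. The q-values of the absent loci in the combined data are not known, so this explanation stays open, and no biological explanation was tested.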
